A study of Arabidopsis thaliana with 8 samples.

How the data were processed

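RNA was taken from whole 10 days old seedlings of 4 groups (mock, ABA, PA and DPA, 50 μM for 3 h) with 2 biological replicates each, 8 libraries in all. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT), copied with random hexamers and sequenced as single reads, and the protocol does not say that the kit marks strand. The submitters' processing notes list TopHat 1.4.1, HTSeq and DESeq 1.8.3 with the TAIR10 genome, without stating the role of each.

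The authors deposited 3 comparison tables, each treatment against mock, and 2 gene lists, with no counts per library. Each table holds 32683 rows, of which 32678 carry a gene and 5 name no gene (the HTSeq totals of unassigned reads). The deposited means are a signal, here called normalized counts: the authors divided counts of reads by a size factor per library and averaged them over the 2 libraries of a group, per the file headers and the spacing of the values. The deposited fold changes are ratios of these means, from which log2 fold changes were computed here. The deposited p-values and adjusted p-values are credited to DESeq, per the submitters' processing notes. The p-values rest on the spread between biological duplicates, and the notes do not say how DESeq shared it over genes. A Benjamini-Hochberg adjustment of the deposited p-values matched the deposited adjusted p to within 3.06e-13. Of the gene rows, 24759 had a value above 0 in any group, and 31912 were found by locus in the TAIR10.1 reference annotation, from which positions and product names were taken. Reads assigned to no gene made 48.2% to 48.5% of the normalized total, and ambiguous reads 0.278% to 0.315%, and both stayed out of all tests.

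The design, written before the data were examined, planned a count model if counts per library were deposited and otherwise the authors' own calls. Since the files hold group means, the main calls are the authors' deposited adjusted p under 0.05, by direction. Differences between compounds were tested per gene with a normal test of the difference of the deposited log2 fold changes, each with the standard error implied by its p (size of the log2 fold change over the normal quantile) and the errors added in quadrature, with Benjamini-Hochberg adjustment. Because mock is shared, the added errors tend to overstate the error of the difference. A p listed as 0 was taken as 1e-300, which makes that standard error an upper bound. The 95% intervals of differences use the same errors.

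Each group mean is a sum of whole reads times 1 step per library, so the reads of both libraries of a group were recovered from the deposited means. Between 99.987% and 99.991% of the values above 0 had a single split, and in simulated group means 91320 of 91320 such values were split right. LHCB1.3 could not be split in mock and DPA, nor RBCS1A in any of the 4 groups. Both stayed out of the limma and camera fits, so camera tested 20 light harvesting and Rubisco genes. The size factors implied by the steps differed by at most 3.16% from median-ratio size factors of the recovered reads. Which library is which replicate cannot be told, so libraries are named by group and size factor: 0.979 and 0.917 in mock, 1.15 and 0.816 with ABA, 1.17 and 0.855 with PA, and 1.00 and 0.968 with DPA. Libraries held 11.4 to 15.8 gene reads in units of 1e6. The replicates differed by more than counting noise: the SD of the log2 difference was 0.336 in mock and 0.228, 0.218 and 0.241 with ABA, PA and DPA. Counting intervals cover counting error only.

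As an alternative chosen after seeing the data, limma 3.58.1 (moderated t test with trend, R 4.3.3) was fitted to log2 of the recovered normalized counts plus 1 in genes with a mean of at least 10, with 4 groups in a single fit, 4 residual degrees of freedom and 5.37 prior ones. In simulated data with 50 genes changed at each size, limma recovered 84%, 92% and 82% of 2-fold changes in the ABA, PA and DPA layouts, with 10, 14 and 16 false calls. The test of differences recovered 80%, 64% and 64% for PA against ABA, DPA against ABA and DPA against PA with 0 false calls. The simulation for the test of differences gave all genes the same fixed dispersion and took its p-values from that known dispersion. Its 0 false calls therefore do not carry over to errors implied by the deposited p-values. Upper-quartile scaling, other pseudocounts and minimum means, fits of only the 2 groups compared, fits without each library in turn and fits with a replicate block were also added after seeing the data.

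The 19 gene lists were fixed before the data were examined: ABA receptors, clade A PP2C, SnRK2 kinases, ABA-related transcription factors, ABA synthesis, ABA catabolism and conjugation, LEA and dehydration-responsive genes, seed storage proteins and oleosins, light harvesting and Rubisco small subunit, alpha-expansins, early auxin response, type-A response regulators, jasmonate, salicylate-associated defence, xenobiotic detoxification, circadian clock, root-enriched markers, guard cell and stomatal lineage markers, and reference genes. For each list and comparison the median deposited log2 fold change of members with a mean of at least 10 was set against 100000 random lists matched on mean expression in 20 bins (two-sided), with Benjamini-Hochberg adjustment over 57 tests. The smallest permutation p possible was 1.00e-05. In simulated lists 1 of 100 passed with no shift and 100 of 100 with a log2 shift of 0.5. Because members vary together, camera in limma was also run with a preset correlation of 0.01 and with an estimated correlation. The same was done, after seeing the data, for 23 aliphatic glucosinolate genes. Calls are also given adjusted over the list alone.

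Genes were named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls of each comparison with mock among genes with an adjusted p under 0.05 and a mean of at least 50; 2 to 4 members of each list by smallest adjusted p or highest mean; the ABA receptors, clade A PP2C and ABA catabolism genes throughout; the 5 largest differences each way between compounds; and the 10 largest changes of the deposited list unique to PA. Genes named for other reasons are said to be chosen after their values were seen. Where a group had no read, a bound is given from a floor of 3 reads over the group, and where mock had 1 to 3 reads a ratio of reads with an exact binomial interval. The covariance expected under shared mock libraries came from 50 simulations without treatment effects. These gave all groups a spread averaged over the 4 groups, although the mock pair lay farthest apart, so the expected covariance may be too low. With groups of 2, no test for outlying samples was run. Of 313 named genes, 11 would have at least 20% of their mean from a gene overlapping them on the other strand, by read density. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.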

Results

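Whole Arabidopsis thaliana seedlings of the Columbia accession, 10 days old, were given abscisic acid (ABA), phaseic acid (PA) or dihydrophaseic acid (DPA) at 50 μM for 3 h, or a mock treatment, and polyadenylated RNA was sequenced. Each of the 4 groups held 2 biological replicates, giving 8 libraries. ABA is the plant hormone of water deficit and seed dormancy. PA arises from ABA by hydroxylation of the 8' carbon by the CYP707A cytochromes P450 and spontaneous ring closure, and DPA is PA with the 4' ketone reduced to a hydroxyl group. The comparisons with mock asked which transcripts each compound changed, and the comparisons among compounds, all at the same dose and time, asked how the responses to the ABA catabolites relate to the response to ABA. Reads assigned to genes, in units of 1e6, were 12.8 and 12.4 in the mock libraries, 15.8 and 11.4 with ABA, 15.4 and 11.4 with PA, and 13.2 and 12.7 with DPA. In each library 22415 to 22761 genes had at least 1 read. Across the 16416 genes with a mean of at least 50 normalized counts, the log2 values of the 2 libraries of a group had a Pearson correlation of 0.981 in mock, 0.991 with ABA, 0.991 with PA and 0.990 with DPA. The mock pair lay farthest apart, with 277 of these genes differing at least 2-fold between its libraries, against 54, 38 and 120 with ABA, PA and DPA. On the first principal component, which held 78.3% of the variance, the ABA libraries lay at 67.5 and 66.4 and the PA libraries at 2.03 and 3.03. On the same component the DPA libraries lay at -36.1 and -35.3 and the mock libraries at -37.8 and -29.9.

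ABA raised transcripts of dehydration protection and of its own signalling phosphatases, and lowered transcripts of its receptors and of cell wall loosening. RD29B (AT5G52300, chromosome 5, 21237021 to 21239531), a hydrophilic stress protein widely used as an ABA marker, went from a mean of 173 to 25535 normalized counts in the authors' deposited table. The recovered ABA libraries held 24838 and 26232 against 208 and 137 in mock. KIN1, a small cold- and ABA-induced protein, rose by 8.13 on the log2 scale, LEA7 and LEA4-5, late embryogenesis abundant (LEA) proteins, by 8.07 and 7.61, and BGLU24, a beta-glucosidase, by 8.05 in the authors' deposited table. The authors' deposited table called 2481 genes higher and 1232 lower with ABA at an adjusted p under 0.05 (DESeq), 3713 of the 24069 tested. The median log2 fold change was 1.19 for the risen genes and -0.79 for the fallen ones, and 1866 of the calls were at least 2-fold. A limma fit to the 8 recovered libraries called 3541 higher and 2800 lower, and with upper-quartile scaling, which lowered the log2 fold changes by a median of 0.09, it called 2956 higher and 4006 lower. The limma total fell from 6341 to 4216 without the ABA library of higher size factor. In the full fit 3623 of the 3640 deposited calls that it tested were called again in the same direction.

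Several of the largest rises started from almost no reads. HAI3, a clade A protein phosphatase 2C (PP2C), had 3 reads over both mock libraries and 1305 with ABA, a ratio of 419.5 with a 95% counting interval of 143 to 2037. MYB41, a transcription factor of cuticle and suberin formation, had 1 mock read and 223 with ABA (ratio 215, 38.2 to 8532). ATHSP22.0, a small heat shock protein, had 1 and 446 (ratio 430.1, 76.8 to 17027), and AT2G32020, an acyltransferase-like protein, 1 and 277 (ratio 267, 47.6 to 10589). AT5G50360, a von Willebrand factor A domain protein, and AT5G28520, a mannose-binding lectin, rose by 7.61 and 7.54 on the log2 scale in the authors' deposited table. The largest falls in the authors' deposited table included the SAUR-like auxin-responsive gene AT4G34770 (log2 fold change -4.81, adjusted p = 1.39e-08), the pectin methylesterase-type gene ATPMEPCRD (-4.43), the acyltransferase AACT1 (-4.40), the methyltransferase-like gene AT1G15125 (-4.40) and the peroxidase gene AT4G11290 (-4.04). AT1G27020, AT5G48430 and AT3G20380 fell as well (-4.96, -4.48 and -4.80 in the authors' deposited table). So did GSTF14, a glutathione transferase, and IMS2, an enzyme of methionine chain elongation (-3.66 and -3.80 in the authors' deposited table). By read density a gene overlapping AT3G20380 on the other strand would give 231% of its mean count. That gene lay at -0.06 with ABA in the authors' deposited table, so it is not the source of the fall. Such a fall beside an unchanged partner also shows that the read-density estimate is too high for AT3G20380.

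The core of ABA perception moved in opposite directions. All 9 clade A PP2C genes, whose products hold back ABA signalling, rose with ABA, also when adjusted over the list alone, with a median log2 fold change of 3.35 (permutation test against random lists of matched expression, two-sided, adjusted p = 5.70e-05). That p is from the smallest the permutations can give, and the call was lost in a test that estimates the correlation among members (adjusted p = 0.259 with an estimated correlation). With the preset correlation of 0.01 it was kept (camera adjusted p = 8.11e-11). Of the 57 list tests camera called 28 with the preset correlation and 0 with an estimated correlation. In the authors' deposited table HAI1 rose by 6.51, HAI2 by 5.89, ABI2 by 3.35 and ABI1 by 2.77 on the log2 scale. Of the 9 measured PYR/PYL/RCAR receptor genes, which bind ABA, 7 fell and 2 were not called. Adjusted over the list alone, 7 fell and 1 rose (median log2 fold change -1.27, adjusted p = 0.000228, and adjusted p = 0.259 with an estimated correlation). PYL4 went from 1990 to 193 normalized counts and PYL5 from 141 to 19.3 in the authors' deposited table, while PYL7 and PYL9 were not called (0.01 and 0.51). PYL7 overlaps a gene on the other strand whose read density would give 22.1% of its mean. Among the 10 SnRK2 kinase genes, 4 rose and none fell, with the same counts adjusted over the list alone. These were SNRK2.7 and OST1, the guard cell kinase of ABA signalling, by 3.31 and 1.61, and SNRK2.1 and SNRK2.10 by 0.54 and 0.47 in the authors' deposited table. The SnRK2 list as a whole did not pass (median 0.30, adjusted p = 0.0579). Of 21 measured ABA-related transcription factors, 17 rose, 19 adjusted over the list alone, and none fell (median 2.34, adjusted p = 5.70e-05, and adjusted p = 0.259 with an estimated correlation). HB-7, RD26 and ABF3 rose by 4.02, 4.53 and 2.92 on the log2 scale in the authors' deposited table.

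Genes of ABA turnover rose as well. All 4 CYP707A genes, which encode the ABA 8'-hydroxylases, rose with ABA, CYP707A1 from 97.5 to 2840 normalized counts and CYP707A3, CYP707A2 and CYP707A4 by 2.61, 2.57 and 1.83 on the log2 scale in the authors' deposited table. In the list of ABA catabolism and conjugation, 5 of 8 measured genes rose and 1 fell, also adjusted over the list alone (median 1.4, adjusted p = 0.000204, and adjusted p = 0.259 with an estimated correlation). The faller was UGT71C5, an ABA glucosyltransferase (-0.63), and BGLU18, which releases ABA from its glucose ester, rose by 0.98 in the authors' deposited table. BGLU18 was no longer called without the ABA library of higher size factor (limma adjusted p = 0.0599) or without that of lower size factor (0.0577). ABH2, the reductase that makes DPA from PA, stood at 2.04 normalized counts in mock, too few to follow. Of 6 measured ABA synthesis genes 3 rose, also adjusted over the list alone (median 0.58, adjusted p = 0.0167, and adjusted p = 0.386 with an estimated correlation). That call was lost with the mean (0.79, adjusted p = 0.0720). NCED3, the stress-induced dioxygenase of the pathway, rose by 2.4, AAO3 by 1.29 and ABA1 by 0.71 in the authors' deposited table. All 25 LEA, dehydrin and other dehydration-responsive genes rose, also adjusted over the list alone (median 4.51, adjusted p = 5.70e-05, and adjusted p = 0.189 with an estimated correlation). RD29A rose by 5.86, RAB18 by 5.43 and COR47 by 3.59 in the authors' deposited table. In the list of seed storage proteins and oleosins, OLEO1 and OLEO2 rose by 1.79 and 2.16 in the authors' deposited table. The other 4 of 6 measured members were not called, with the same counts adjusted over the list alone (median 0.99, adjusted p = 0.00914, and adjusted p = 0.740 with an estimated correlation). With the mean, 0.71, the list did not pass (adjusted p = 0.180). SESA1 and SESA2, seed albumins, were uneven between mock libraries: their limma log2 fold changes turned to 2.23 and 3.26 without the mock library of lower size factor (adjusted p = 0.0333 and 0.0102), against -1.42 and -0.24 in the authors' deposited table.

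Detoxification genes rose with ABA. Of 17 measured xenobiotic detoxification genes, 12 rose and none fell (14 rose and 1 fell adjusted over the list alone), with a median of 2.00 (adjusted p = 5.70e-05, and adjusted p = 0.259 with an estimated correlation). UGT74E2, which glucosylates indole-butyric acid, went from 10.2 to 786 normalized counts and GSTU25, a glutathione transferase, rose by 3.75 on the log2 scale in the authors' deposited table. GSTU3, which had no read in mock and stayed outside the list test, rose to 39.0 normalized counts in the authors' deposited table. Of 22 measured jasmonate synthesis and response genes, 9 rose and none fell, 11 and 1 adjusted over the list alone (median 0.57, adjusted p = 8.77e-05, and adjusted p = 0.574 with an estimated correlation). With the mean, 0.54, the list did not pass (adjusted p = 0.0537). JAZ1, a repressor of jasmonate signalling, rose by 2.39 and MYC2, a transcription factor it binds, by 0.99 in the authors' deposited table. JAZ7, LOX2 and AOC1, called higher in that table (1.96, 0.97 and 0.94), were not called in some limma fits lacking a library. JAZ7 was lost without the ABA library of higher or of lower size factor (adjusted p = 0.134 and 0.0911) or the mock library of higher or of lower size factor (0.0596 and 0.0697). LOX2 was lost without the ABA library of lower size factor (0.0644) and AOC1 without that of higher size factor (0.0685). Of 9 measured salicylate-associated defence genes only WRKY33 rose, by 1.93 in the authors' deposited table, 1 of 9 adjusted over the list alone. The median of that list was 0.06, which turns to -0.04 with the upper-quartile shift, its mean was -0.36, and its test did not pass (adjusted p = 0.775).

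Most alpha-expansin genes fell with ABA. Of 17 measured alpha-expansin genes, whose products loosen cell walls, 11 fell and 1 rose, with the same counts adjusted over the list alone (median -1.10, adjusted p = 5.70e-05, and adjusted p = 0.259 with an estimated correlation). EXPA1 went from 6903 to 1458 normalized counts and EXPA8 from 3403 to 927 in the authors' deposited table, whereas EXPA16 rose by 5.09. EXPA2, at -3.31 in the authors' deposited table, was not called by limma (adjusted p = 0.0603), and EXPA11 (-0.43) was not called without the ABA library of higher size factor (0.0741). Of 7 measured type-A response regulators, cytokinin-induced genes, 3 fell, also adjusted over the list alone (median -1.71, adjusted p = 0.000456, and adjusted p = 0.574 with an estimated correlation). ARR7, ARR5 and ARR4 fell by 2.67, 2.36 and 1.71 in the authors' deposited table. The early auxin response list split, 4 of 16 measured genes rising and 3 falling, also adjusted over the list alone (median -0.12, adjusted p = 0.550). IAA7 and IAA4 fell by 0.60 and 0.63 and IAA13 and IAA14 rose by 0.69 and 0.61 in the authors' deposited table. Limma kept 4 of the 7 calls without the ABA library of lower size factor, losing IAA19 (adjusted p = 0.0663), GH3.3 (0.0732) and GH3.5 (0.0613). It kept 5 without that of higher size factor, losing IAA19 (0.0521) and GH3.5 (0.0734), and lost IAA19 without the mock library of higher size factor (0.0627). Of 22 light harvesting and Rubisco small subunit genes, RBCS1B and RBCS2B fell, by 0.91 and 0.52 in the authors' deposited table. The other 20 were not called, with the same counts adjusted over the list alone (median -0.32, adjusted p = 0.0457, and adjusted p = 0.729 with an estimated correlation). Their mean of -0.33 did not pass (adjusted p = 0.136). RBCS2B was not called without the ABA library of higher size factor (limma adjusted p = 0.0629). Of 12 circadian clock genes ELF4 and TOC1 rose, by 0.85 and 0.40 in the authors' deposited table, also adjusted over the list alone (median 0.15, adjusted p = 0.260). TOC1 was not called without the ABA library of higher size factor (limma adjusted p = 0.0918).

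Markers of other tissues of the seedling moved little as sets. Of 11 root-enriched markers 2 fell, also adjusted over the list alone (median -0.19, adjusted p = 0.476). IRT1, the root iron transporter, had no read in the ABA libraries and was at least 53.9-fold lower than its mock mean of 84.7 (floor of 3 reads over the group). PYK10, a root beta-glucosidase, fell by 0.45 in the authors' deposited table, a call that limma did not make (adjusted p = 0.0810). Of 6 guard cell and stomatal lineage markers, MYB60 and KAT1 fell by 1.05 and 0.61 in the authors' deposited table and 4 were not called, also adjusted over the list alone (median -0.28, adjusted p = 0.264). Among 8 commonly used reference genes, ACT2 and EF1A fell by 0.55 and 0.37 and UBQ10 and SAND rose by 0.42 and 0.44 in the authors' deposited table, with the same counts adjusted over the list alone. UBQ10 was not called without the ABA library of lower size factor (limma adjusted p = 0.0578) and EF1A without that of higher size factor (0.101). The median of the reference genes was 0.02, which turns to -0.07 with the upper-quartile shift, and their mean -0.01 (adjusted p = 0.677).

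**Figure D1:**
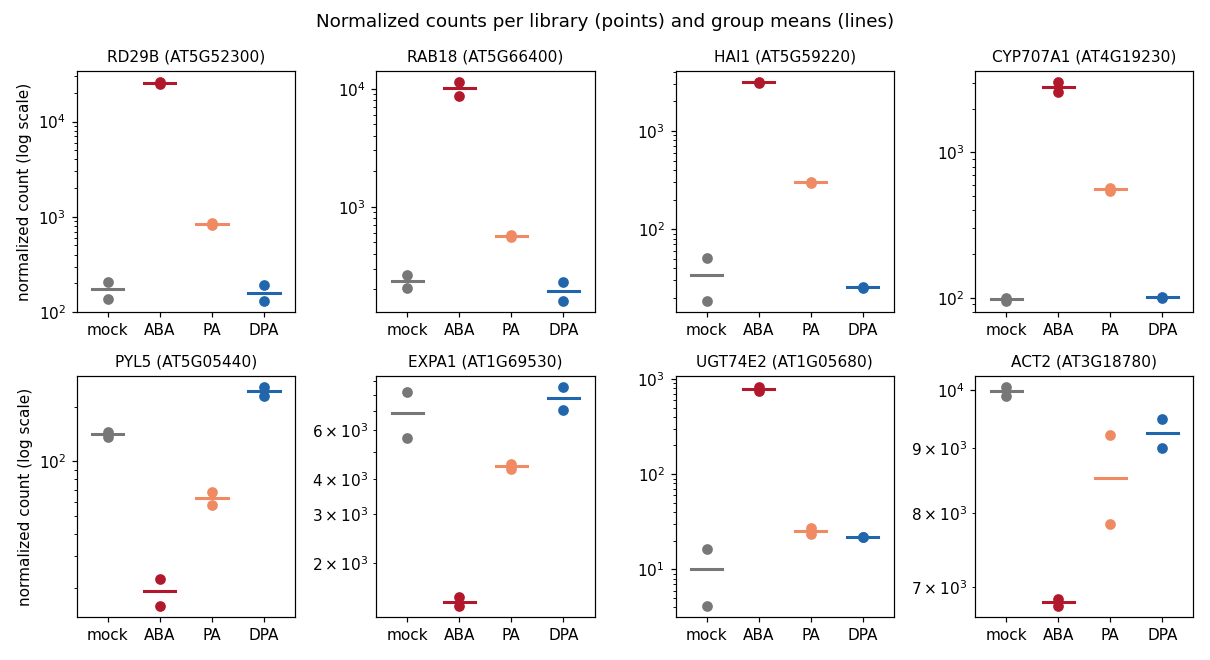
Normalized counts (log axis) of 8 genes in each of the 8 recovered libraries, grouped by treatment; each point is 1 library. RD29B lies at 24838 and 26232 with ABA, 813 and 863 with PA, 190 and 130 with DPA and 208 and 137 in mock, while PYL5 lies at 15.9 and 22.6 with ABA and 257 and 231 with DPA.

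PA raised much of the same dehydration and signalling set to smaller levels and left most other transcripts uncalled. In the authors' deposited table RD29B went from 173 to 838 normalized counts, HAI1 from 34.3 to 299 and CYP707A1 from 97.5 to 556, with 813 and 863, 303 and 295, and 544 and 569 in the recovered PA libraries. The authors' deposited table called 283 genes higher and 35 lower with PA at an adjusted p under 0.05 (DESeq), 318 of 23985 tested, with median log2 fold changes of 1.65 and -0.78. The largest rises in that table were of BGLU24 (4.85), MRN1, which makes the triterpene marneral (4.27), AT1G49450, a WD40 repeat protein (4.19), KIN1 (4.11), LTI30, a dehydrin (4.07), and HSFA6B, a heat shock transcription factor (4.03). Next in the authors' deposited table came AT2G34610 (3.90), PELPK2, a hydroxyproline-rich glycoprotein (3.79), LEA4-5 (3.72) and CHX17, a cation/proton exchanger of roots (3.70). The largest falls in the authors' deposited table were of the monodehydroascorbate reductase gene MDHAR (-2.38), the glutaredoxin genes AT1G06830 and GRXS13 (-2.09 and -2.04), AZI1, a lipid-transfer protein of systemic defence (-1.50), and XTH18, a xyloglucan-modifying enzyme (-1.47). Next in the authors' deposited table came AT2G22122 (-1.37), ERD5, the proline dehydrogenase gene (-1.26), PYL5 (-1.17), the transporter gene ABCB21 (-1.12) and ARR4 (-1.02). By limma 361 genes were higher and 62 lower with PA, 365 and 60 with upper-quartile scaling, and 280 of the 318 deposited calls were among the first set. AT1G06830, AZI1 and AT2G22122 were not called by limma (adjusted p = 0.0944, 0.242 and 0.162). The limma count was 1111 without the mock library of lower size factor, 146 without the PA library of higher size factor and 126 without that of lower size factor, of which 280, 120 and 116 were among the 318. Without the PA library of higher and of lower size factor limma no longer called the falls of MDHAR (adjusted p = 0.101 and 0.144), GRXS13 (0.107 and 0.286), XTH18 (0.119 and 0.232), PYL5 (0.165 and 0.0975), ABCB21 (0.204 and 0.138) and ARR4 (0.0850 and 0.163). The same 6 were lost without the mock library of higher size factor (0.0656, 0.156, 0.0837, 0.0755, 0.0937 and 0.0513).

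In every list with calls fewer members were called with PA than with ABA. Of the 9 clade A PP2C genes 7 rose with PA and 8 adjusted over the list alone (median 0.96, adjusted p = 5.70e-05, and adjusted p = 0.259 with an estimated correlation), HAI1 by 3.12, HAI2 by 2.44 and ABI1 by 0.88 in the authors' deposited table. Without the PA library of lower size factor limma kept 3 of the 7 and lost HAI3 (adjusted p = 0.174), ABI2 (0.138), HAB1 (0.0975) and PP2CA (0.114). Without that of higher size factor it kept 4 and lost HAI3 (0.0992), ABI2 (0.155) and PP2CA (0.243). HAI3 had 76 reads with PA against 3 in mock (ratio 23.7, 7.82 to 118). PYL4 and PYL5 fell, by 0.90 and 1.17 in the authors' deposited table, and 7 receptors were not called (3 fell adjusted over the list alone, median -0.41, adjusted p = 0.000456, and adjusted p = 0.259 with an estimated correlation). Of 25 LEA and dehydration-responsive genes 20 rose, 23 adjusted over the list alone (median 1.35, adjusted p = 5.70e-05, and adjusted p = 0.161 with an estimated correlation), among them LTI30, RD29A (2.41) and ERD10 (1.29) in the authors' deposited table. Without the PA library of higher or of lower size factor limma kept 12 of the 20 and lost RAB18 (adjusted p = 0.0850 and 0.106), COR15A (0.152 and 0.174), KIN2 (0.161 and 0.163), RD20 (0.113 and 0.174), EM1 (0.243 and 0.115), EM6 (0.245 and 0.163), P5CS1 (0.291 and 0.233) and HVA22D (0.0756 and 0.117). Of 21 transcription factors 8 rose, 10 adjusted over the list alone (median 0.82, adjusted p = 5.70e-05, and adjusted p = 0.256 with an estimated correlation), HB-7 by 1.74 and ABF3 by 1.18 in the authors' deposited table. MYB41 had 61 reads with PA against 1 in mock (ratio 57.2, 9.88 to 2295). Of 8 catabolism and conjugation genes only CYP707A1 rose, by 2.51 in the authors' deposited table, and 2 rose adjusted over the list alone (median 0.46, adjusted p = 0.000456, and adjusted p = 0.218 with an estimated correlation). Of the 6 synthesis genes none was called, and 1 rose adjusted over the list alone (median 0.16, adjusted p = 0.0620). None of the 10 SnRK2 genes was called, nor was any adjusted over the list alone, although the list lay above matched lists (median 0.16, adjusted p = 0.0159, and adjusted p = 0.299 with an estimated correlation). The mean of the SnRK2 list, 0.24, did not pass (adjusted p = 0.0979). OLEO2 rose by 1.65 in the authors' deposited table and was the 1 called of 6 seed genes, 2 adjusted over the list alone (median 0.84, adjusted p = 0.000456, and adjusted p = 0.684 with an estimated correlation). The mean of the seed list, 0.18, did not pass (adjusted p = 0.484). Limma did not call OLEO2 with PA (adjusted p = 0.0673), and without the PA library of higher size factor it did not call PYL4 (0.0536) or PYL5 (0.165).

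Outside these lists few members passed with PA. ARR4 fell by 1.02 in the authors' deposited table and was the 1 of 7 type-A response regulators called, 3 adjusted over the list alone (median -1.02, adjusted p = 8.77e-05, and adjusted p = 0.379 with an estimated correlation). Of 17 expansins EXPA16 rose, by 2.03 in the authors' deposited table, and none fell, while adjusted over the list alone 1 rose and 2 fell (median -0.25, adjusted p = 0.000456, and adjusted p = 0.574 with an estimated correlation). The mean of the expansins, -0.25, did not pass (adjusted p = 0.0720). JAZ1 rose by 0.98 in the authors' deposited table, the 1 of 22 jasmonate genes called and the 1 called adjusted over the list alone (median 0.22, adjusted p = 8.77e-05, and adjusted p = 0.444 with an estimated correlation). The jasmonate mean, 0.21, did not pass (adjusted p = 0.0907). Limma did not call JAZ1 without the PA library of lower size factor (adjusted p = 0.0996). No detoxification gene of 17 was called, 2 rose adjusted over the list alone, and the list lay above matched lists (median 0.36, adjusted p = 5.70e-05, and adjusted p = 0.386 with an estimated correlation). In the remaining 7 lists no member was called with PA, over all genes or adjusted over the list alone. Of these, light harvesting and clock genes lay above matched lists (medians 0.08 and 0.14, adjusted p = 0.00620 and 0.00825), with adjusted p = 0.976 and adjusted p = 0.574 with an estimated correlation. Their means of 0.04 and 0.08 did not pass (adjusted p = 0.541 and 0.400). Salicylate and root genes passed only with the mean (-0.45 and -0.48, adjusted p = 0.0495 and 0.0460). Their lowest members lay at -4.36 and -3.62, so these means lean on single genes that were not called, and no shift of the whole lists is shown. Auxin response, salicylate, root, guard cell and reference genes had medians of 0.03, -0.01, -0.05, 0.09 and -0.04 (adjusted p = 0.476, 0.943, 0.767, 0.284 and 0.849).

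The genes changed by PA were almost all genes changed by ABA. Of the 283 genes risen with PA, 273 rose with ABA, where independent lists would share 29.7, and of the 35 fallen genes 34 fell with ABA, where independent lists would share 1.83. Of the other PA calls 10 were not called with ABA and 1 was opposite. MYB29, a transcription factor of aliphatic glucosinolate synthesis, chosen after its values were seen, was lower with ABA and higher with PA (log2 fold changes -1.08 and 0.52 in the authors' deposited table). Limma did not call MYB29 with PA (adjusted p = 0.246), where the recovered libraries held 1071 and 1102 against 664 and 847 in mock. By limma the overlap was 416 genes, with 1037 without the mock library of lower size factor, 145 without the PA library of higher size factor and 123 without that of lower size factor. Across the 16416 genes with a mean of at least 50, which are not independent replicates, the log2 fold changes of PA and ABA had r = 0.816 and rho = 0.674. Both share the 2 mock libraries, which gave a covariance of 0.0122 in 50 simulations without treatment effects against an observed covariance of 0.228, so part of the correlation may come from the shared controls. The 0.0122 may be too low, since the simulations gave mock the average spread of all groups and the mock pair lay farthest apart. With ABA and PA set against different mock libraries, 1 each, r was 0.648 and 0.621 and the covariance 0.192 and 0.201. Of genes with a mean of at least 50, 1050 were called at least 2-fold higher with ABA. Their median log2 fold change was 1.73 with ABA and 0.53 with PA, and 97.0% lay above 0 with PA. Under the same limit 349 genes were called at least 2-fold lower with ABA. Their median was -1.39 with ABA and -0.36 with PA, with 90.5% below 0 with PA.

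**Figure D2:**
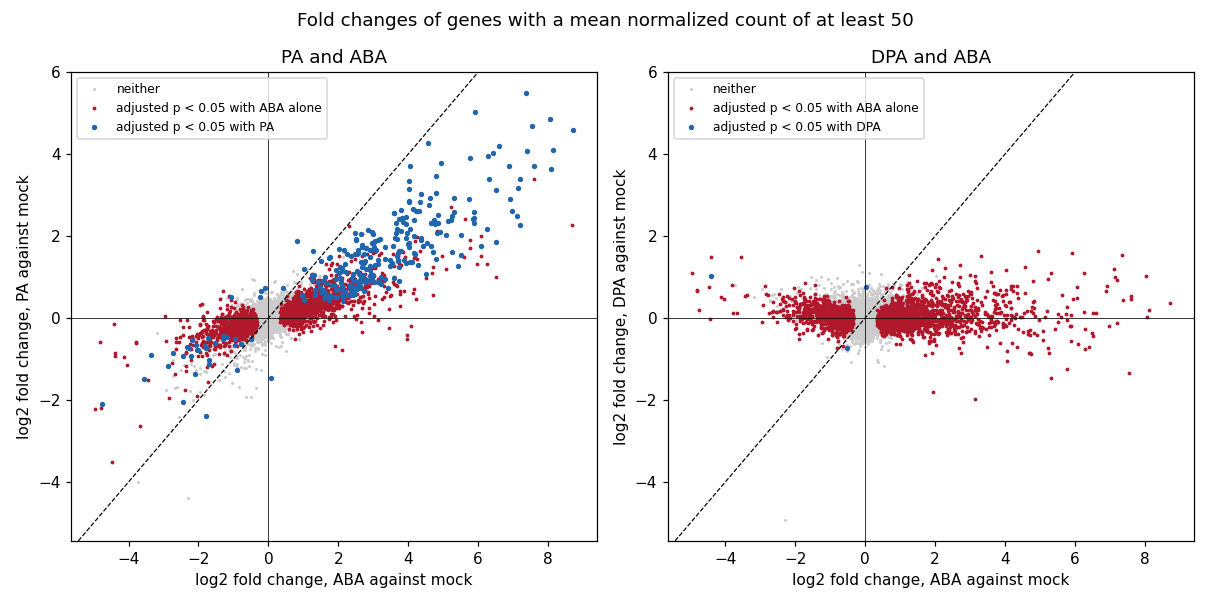
Log2 fold changes against mock of PA (left) and DPA (right) on the vertical axis against those of ABA on the horizontal axis, 1 point per gene with a mean of at least 50 normalized counts. PA values rise with ABA values at a lower slope (r = 0.816 across genes, covariance 0.228, with 0.0122 from simulated shared controls alone), and DPA values do not (r = 0.04). The simulated covariance may be too low, since the mock libraries varied more than the simulations assumed.

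At matched dose and time PA gave weaker changes than ABA. The test of the difference of the 2 log2 fold changes called 727 genes lower and 250 higher with PA than with ABA, of 20618 tested (normal test, standard errors implied by the deposited p-values, adjusted p under 0.05). RD29B was lower with PA, with a log2 difference of -4.93 (standard error 0.26, adjusted p = 2.61e-74). So were SAG29, a sugar transporter of senescence (-5.52, 0.51, 6.54e-24), UGT74E2 (-4.95, 0.70, 3.56e-10), CYP76C2, a cytochrome P450 (-4.64, 0.96, 9.21e-05), and the LEA-family gene AT3G02480 (-4.63, 0.37, 1.77e-32). Higher with PA were AT4G34770 by 4.23 (0.87, 8.62e-05), AACT1 by 3.54 (0.67, 1.41e-05), AT1G15125 by 3.47 (0.53, 6.88e-09), IMS2 by 3.22 (0.82, 0.00344) and the SAUR-like gene AT4G34790 by 3.19 (0.64, 5.46e-05). Of the lists, 23 of 25 LEA and dehydration-responsive genes, 8 of 9 clade A PP2C genes, 12 of 20 testable transcription factors, 9 of 17 detoxification genes and 3 of 8 catabolism genes were lower with PA than with ABA, and 4 of 9 receptors were higher. PYL4 was higher with PA by 2.47 (0.21) and CYP707A1 lower (-2.35, 0.34). By limma 1439 genes were higher and 2470 lower with PA than with ABA, and 2502 and 1906 with upper-quartile scaling, and 976 of the 977 calls were among the first set. The limma total of 3909 fell to 2243 and 2295 without the PA library of higher and of lower size factor and to 2249 and 2382 without the ABA library of higher and of lower size factor.

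Some genes could not be told apart between ABA and PA. MRN1 rose by 4.58 with ABA and 4.27 with PA in the authors' deposited table, a difference of -0.31 with a 95% interval of -2.30 to 1.67, and CHX17 by 4.04 and 3.70 (-0.34, -1.50 to 0.82). For ERD5 the difference was -0.38 (-1.01 to 0.26) and for OLEO2 -0.51 (-1.30 to 0.29). These intervals leave room for differences of 2-fold and more in at least 1 direction. The authors' deposited list of genes unique to PA held 12 genes, each with an adjusted p under 0.1 with PA and not with ABA, and this list was chosen on these samples. Of its members XTH18 had a difference of -1.56 (-3.31 to 0.19) and LAC7, a laccase, of 0.36 (-0.90 to 1.62). AT1G14120, a dioxygenase-like gene, and JAL33, a lectin, were higher with PA than with ABA by 0.82 and 0.76 (standard errors 0.25 and 0.20, adjusted p = 0.0243 and 0.00461). OSM34, an osmotin, rose by 0.81 with ABA and 1.89 with PA in the authors' deposited table (difference 1.08, standard error 0.31, adjusted p = 0.0152). With MYB29 these were the 4 genes called with PA that also differed from ABA in the direction of the PA change. OSM34 was chosen after its values were seen. Without the PA library of higher size factor limma did not call AT1G14120 or JAL33 against mock (adjusted p = 0.136 and 0.150), nor LAC7 (0.292). ANNAT7, AT1G74460, AT5G10770 and AK3 of the deposited list rose with PA by 1.69, 1.68, 0.74 and 0.67 in the authors' deposited table and were not called by limma (adjusted p = 0.167, 0.0524, 0.0596 and 0.139). The members AT1G03700, MSRB7, AT1G18980 and HMT3 had an adjusted p with PA between 0.05 and 0.1 in the authors' deposited table (adjusted p = 0.0740, 0.0636, 0.0924 and 0.0921). The deposited list shared by ABA and PA held 333 of the 362 genes with an adjusted p under 0.1 in both tables.

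DPA left nearly all transcripts uncalled. The authors' deposited table called 2 genes higher and 1 lower with DPA, of 23970 tested, and 220 genes had an unadjusted p under 0.05 (DESeq). That is a smaller share than 0.05, which calibrated p-values would give without any change. The deposited p-values, and the errors implied by them, may thus be too large, and few calls do not show that DPA changed nothing. AT1G15125 (chromosome 1, 5204312 to 5205964) went from 667 to 1370 normalized counts (log2 fold change 1.04, adjusted p = 2.82e-08) and the legume lectin gene AT3G15356 from 407 to 685 (0.75, 0.0355) in the authors' deposited table. AT3G09250 fell from 2698 to 1615 (-0.74, 0.000137) in the authors' deposited table. It overlaps PYK10 on the other strand, whose read density would give 98.1% of its mean and which lay at 0.05 with DPA in the authors' deposited table. PYK10 is therefore not the source of the fall. The 2224 counts estimated from PYK10 exceed the 1615 with DPA, so that estimate is too high for AT3G09250. In the recovered libraries AT1G15125 held 578 and 757 in mock and 1417 and 1324 with DPA, and AT3G15356 held 361 and 453 against 646 and 723. Limma called no gene with DPA, with 1082 at an unadjusted p under 0.05, and this held in the other limma settings and omissions but 1. Without the mock library of higher size factor it called 123, among them AT1G15125 and AT3G15356 (adjusted p = 0.0324 and 0.0115). The dehydration markers stayed near mock, with RD29B at 160 against 173 and RAB18 at 195 against 235 normalized counts in the authors' deposited table.

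No member of the 19 lists was called with DPA over all genes. Adjusted over the list alone, 2 receptor genes, 1 jasmonate gene and 1 salicylate gene rose. The receptor list lay above matched lists (median 0.28, adjusted p = 0.00142, and adjusted p = 0.259 with an estimated correlation), with PYL4 at 0.56 and PYL5 at 0.79 in the authors' deposited table. The clade A PP2C list lay below (median -0.21, adjusted p = 0.000841, and adjusted p = 0.574 with an estimated correlation), but its mean of -0.01 did not pass (adjusted p = 0.835). Detoxification (median 0.43, adjusted p = 5.70e-05, and adjusted p = 0.379 with an estimated correlation), root-enriched (0.27, adjusted p = 0.00825, and adjusted p = 0.748 with an estimated correlation) and early auxin response genes (0.12, adjusted p = 0.0101, and adjusted p = 0.684 with an estimated correlation) lay above. The root list did not pass with members of a mean of at least 50 (median 0.01, adjusted p = 0.831) or with the mean (0.30, adjusted p = 0.0590), nor did the auxin list with the mean (0.12, adjusted p = 0.0907). Seed and salicylate genes passed only with the mean (-0.54 and -0.23, adjusted p = 0.00301 and 0.0447). The salicylate mean leans on 1 gene at -2.68 that was not called. LEA and dehydration-responsive genes had a median of 0.01, transcription factors -0.02, catabolism genes 0.07, synthesis genes -0.05, SnRK2 genes -0.01 and seed genes -0.05 (adjusted p = 0.550, 0.618, 0.368, 0.550, 0.849 and 0.558). Expansins had a median of 0.09, type-A response regulators -0.01, light harvesting genes 0.00, jasmonate genes 0.05, salicylate genes -0.04, clock genes -0.02, guard cell markers 0.01 and reference genes -0.02 (adjusted p = 0.0784, 0.863, 0.550, 0.233, 0.550, 0.840, 0.840 and 0.943). Median and mean differed in sign with DPA for the SnRK2 and reference lists, whose means were both 0.00.

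**Figure D3:**
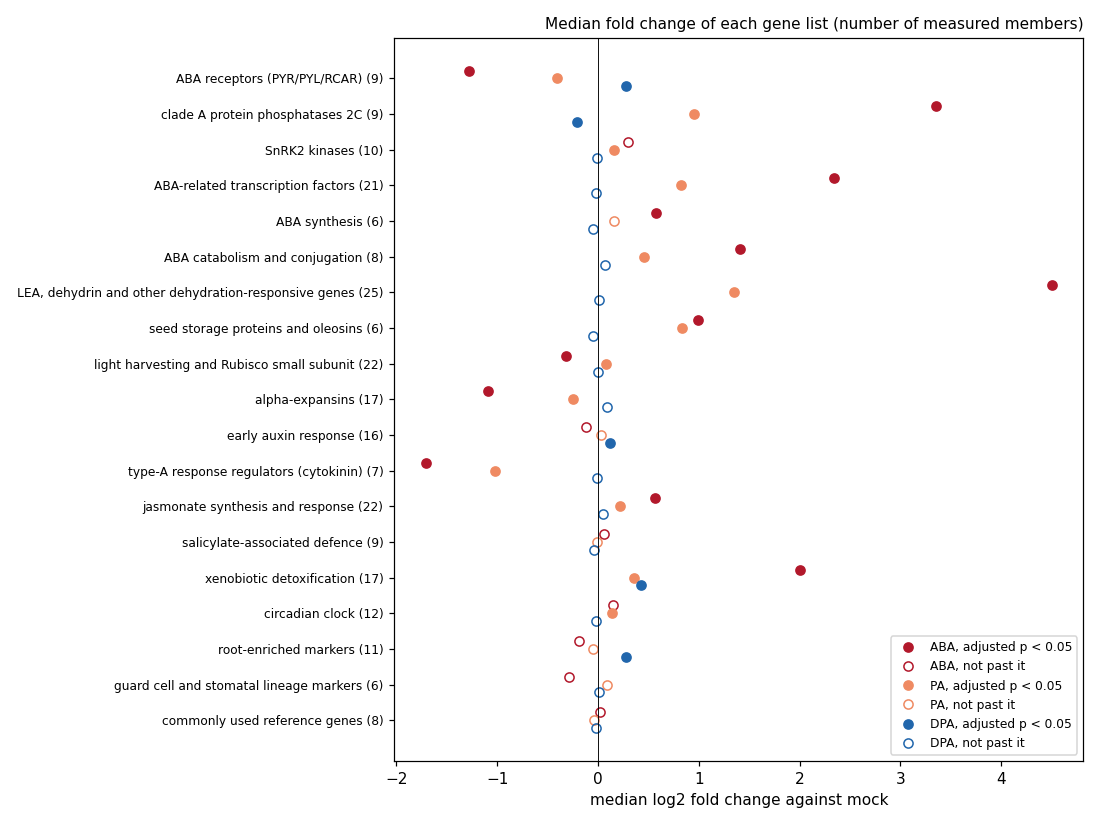
Median log2 fold change against mock (horizontal axis) of the 19 gene lists (vertical axis, measured members in brackets) with ABA, PA and DPA; filled points passed the permutation test at an adjusted p under 0.05. The clade A PP2C list lies at 3.35, 0.96 and -0.21 and the receptors at -1.27, -0.41 and 0.28. With the upper-quartile shift only the ABA medians of the salicylate and reference lists and the DPA median of the light harvesting list, none of them past the test, change sign.

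The responses to DPA differed from those to ABA and PA at the same dose. The test of the difference called 605 genes higher and 1163 lower with DPA than with ABA, of 20426 tested, and 13 higher and 52 lower with DPA than with PA, of 20266. RD29B was lower with DPA than with ABA (log2 difference -7.32, standard error 0.49, adjusted p = 1.89e-47) and lower than with PA (-2.39, 0.48, 0.000530). LEA7, KIN1, TSPO, a membrane protein that binds heme, and LEA4-5 were lower than with ABA (-8.05, -7.94, -7.16 and -7.15). AT1G27020, AACT1, AT4G34770 and AT1G15125 were higher than with ABA by 6.07, 5.90, 5.47 and 5.44. AT3G20380 was higher than with ABA by 5.49. Of the lists, 23 of 24 testable LEA and dehydration-responsive genes and 7 of 8 testable PP2C genes were lower with DPA than with ABA, and 10 and 3 of them lower than with PA. PYL4 was higher with DPA than with ABA by 3.93 (0.23) and than with PA by 1.46 (0.21, adjusted p = 1.99e-08). HAI1, AT1G49450, LTI30 and CHX17 were among the genes lower with DPA than with PA, and AT1G06830, ABCB21, PYL5, AACT1 and AT1G15125 among those higher. By limma the counts were 3044 higher and 3646 lower against ABA, 4087 and 3016 with upper-quartile scaling, and 274 and 480 against PA. The limma total of 754 against PA was 1797 and 1809 without the mock library of higher and of lower size factor, 456 and 463 without those of ABA. It was 172 and 186 without those of PA and 245 and 336 without those of DPA. An error taken from genes of like expression called 172 higher and 115 lower. Across genes the fold changes of DPA had r = 0.04 with those of ABA and r = 0.10 with those of PA. The covariances were 0.00689 and 0.00691, against 0.0122 from simulated shared controls alone, a value that may be too low. With different mock libraries the r values were -0.193 and 0.07 against ABA and -0.359 and 0.07 against PA.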

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

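Both results here were flagged by a difference between groups, a gene called in opposite directions by 2 compounds. The tests of technical explanations were chosen after the results were seen. MYB29 was called lower with ABA and higher with PA, with log2 fold changes of -1.08 and 0.52 in the authors' deposited table, and the difference of PA from ABA was 1.60 (standard error 0.33, adjusted p = 9.79e-05). AT1G15125 was called lower with ABA and higher with DPA, with log2 fold changes of -4.40 and 1.04 in the authors' deposited table, and the difference of DPA from ABA was 5.44 (standard error 0.47, adjusted p = 2.02e-28).

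MYB29 acts with MYB28 on the genes of aliphatic glucosinolate synthesis, and 23 such genes, chosen after its values were seen, had a median log2 fold change of -0.80 with ABA and 0.37 with PA, 21 of them above 0 with PA. A test that estimates the correlation among members gave p = 0.165 with ABA and 0.182 with PA for the 23 genes. For 22 without MYB29 it gave 0.186 with PA. It cannot decide here, since it did not pass even the LEA list with ABA (adjusted p = 0.189). With the preset correlation of 0.01 camera gave p = 3.37e-08 with PA, and 1.04e-07 without MYB29. These may be too small, since the estimated correlation was 0.604 and 0.593. A weaker ABA response of the same sign would put the PA median below 0, and 0.37 lies above it. But 0.37 is within the 0.41 by which the mock libraries differed over these genes, so that response is left open. The lower PA library lay above the higher mock library by a median log2 ratio of 0.13, and 19 of 23 genes had both PA libraries above both mock libraries, against 19.7% of all genes, but 0.13 is within the 0.41 by which the mock libraries differed over these genes, so a difference between the mock libraries cannot be told apart. Limma called 21 of the 23 genes between PA and ABA and 0 between PA and mock, and it did not call MYB29 with PA (adjusted p = 0.246). The direction with PA is left open, and new replicates would be needed to test it.

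The 349 genes with a mean of at least 50 that were called at least 2-fold lower with ABA, among them AT1G15125, had a median log2 fold change of 0.13 with DPA. A chance value of the shared mock libraries would move DPA in the direction of ABA, below 0, and 0.13 lies above it. The medians of the 4 library pairs ran from 0.0801 to 0.160, all farther from 0 than the -0.07 between the mock libraries, though the lowest only narrowly. The 1050 genes with a mean of at least 50 that were called at least 2-fold higher with ABA had a median of 0.03 with DPA, with pairs from -0.04 to 0.10. The shift of the fallen genes is small, and limma called 0 genes with DPA. Weak differences in handling or in endogenous ABA signalling are hypotheses that were not tested and that these files cannot separate. The genes risen with ABA showed no opposite shift, with 55.5% of them above 0 with DPA.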

How the results depend on the processing

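With the settings chosen before the data were examined the PA calls numbered 220 to 374, the ABA calls 2731 to 4441 apart from the 2-fold limit, and the overlap 212 to 361. Of the 30 list calls 17 were kept with the mean in place of the median, 13 lost and 4 gained, 27 kept with members of a mean of at least 50 and 30 with centred fold changes. No called list changed sign. The recovered libraries carry no replicate number, so a replicate block was fitted in limma for all 8 assignments of libraries to numbers, which cannot be chosen between. It called 5869 to 6577 genes with ABA, 303 to 601 with PA, 0 with DPA, 3462 to 4220 for PA against ABA, 6220 to 6952 for DPA against ABA, 468 to 1201 for DPA against PA and 299 to 584 in the overlap. The plan tied the count model to deposited counts, so by choice none was fitted to the recovered reads, although these are whole numbers. Not run for that reason were RLE size factors, the Wald test, the low-count filter, each replicate left out, the replicate block and the fit of 2 groups in a count model. The limma settings, the replicate block in limma, the split mock libraries and camera were added after seeing the data. At least 2-fold changes left 1866 genes with ABA and 1 with DPA, by construction. Limma called 6341 genes with ABA, 6318 with a pseudocount of 0.25, 6329 with no minimum mean, 5711 with a minimum of 50 and 6962 with upper-quartile scaling, and 0 with DPA in each of these settings. In the same order it called 3909, 3864, 3693, 3659 and 4408 between PA and ABA (4628 with only those 2 groups), 6690, 6672, 6726, 6071 and 7103 between DPA and ABA (7297), and 754, 715, 598, 662 and 751 between DPA and PA (1662). Against mock, fits of only the 2 groups compared called fewer genes, 4959 with ABA, 241 with PA and 0 with DPA. The full fit called 6341, 423 and 0. Errors from genes of like expression gave 287 between DPA and PA. The cause was not tested. The correlation of ABA and PA was 0.782 with a minimum mean of 10, 0.674 as rho, and 0.648 and 0.621 with split mock libraries, and the cause was not tested. Of 57 list tests camera called 28 with the preset correlation and 0 with an estimated correlation, and the cause was not tested. With 4 residual degrees of freedom the estimated form did not pass even the LEA list with ABA (adjusted p = 0.189), where all 25 genes rose. A list lost in that form is therefore not shown to be unchanged. In leave-one-out limma fits, where a lone library is assumed to vary like the other groups, the counts ranged from 4216 to 6079 for ABA, 126 to 1111 for PA, 0 to 123 for DPA, 2243 to 4804 for PA against ABA, 4588 to 7557 for DPA against ABA, 172 to 1809 for DPA against PA and 123 to 1037 for the overlap. SESA1 and SESA2 turned from -1.42 and -0.24 to 2.23 and 3.26 with ABA without the mock library of lower size factor, and were -2.31 and -1.16 without that of higher size factor, and the cause was not tested.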

Other observations

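Gene families by product name, chosen after the results were seen, show what else ABA and PA changed (47 families, Fisher exact tests against 19614 genes, Benjamini-Hochberg over 188 tests). These tests take genes as independent, although members of a family can vary together and all calls rest on the same few libraries. The p-values may therefore be too small and serve as description only. With ABA, 32 of 103 pectin enzymes (adjusted p = 2.21e-12), 16 of 50 SAUR auxin-induced proteins (1.0e-06) and 32 of 200 leucine-rich repeat proteins (2.34e-05) fell, against 6.25% of all genes. So did 11 of 21 expansins (4.04e-07), 16 of 93 ribosomal proteins (0.00282), 11 of 52 GDSL lipases (0.00411), 16 of 109 receptor-like kinases (0.0102), 5 of 18 proteins with glucosinolate in the name (0.0307) and 6 of 27 tubulins (0.0376). Extensins and proline-rich proteins (8 of 154, adjusted p = 1.00) and xyloglucan endotransglucosylases (5 of 22, 0.0599) did not pass. AT4G34790, a SAUR-like gene, fell by 3.79 in the authors' deposited table. Many UDP-glycosyltransferases (37 of 104, adjusted p = 3.52e-08), NAC transcription factors (19 of 49, 5.30e-05), lipid-transfer proteins (21 of 67, 0.000602), cytochromes P450 (34 of 151, 0.00455), ABC and multidrug transporters (20 of 73, 0.00466), protein phosphatases 2C (16 of 54, 0.00546), oleosins (5 of 8, 0.0102) and heat shock factors (6 of 12, 0.0128) rose with ABA, against 12.3% of all genes, among them LTP4 (6.91), HSFA6A (4.69) and NAC032 (3.74) in the authors' deposited table. Pentatricopeptide repeat proteins, which act in organelle RNA processing, were rarely called with ABA, with 0 of 238 risen (adjusted p = 3.20e-12) and 3 fallen (0.00449). Few rose among leucine-rich repeat proteins (6 of 200, 0.000130), ribosomal proteins (1 of 93, 0.00181), RNA helicases (0 of 65, 0.00455) and photosystem proteins (0 of 45, 0.0362). The GDSL lipases and lipid-transfer proteins did not move as whole families with ABA. Their median log2 fold changes were 0.03 and 0.02, and both turn to -0.07 with the upper-quartile shift.

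With PA the families with more risen genes than the 1.44% of all genes were lipid-transfer proteins (12 of 67, adjusted p = 1.20e-08), laccases (3 of 15, 0.0102), cytochromes P450 (8 of 151, 0.0128) and NAC factors (4 of 49, 0.0376), while glutaredoxins and thioredoxins (3 of 58, 0.00235) and lipid-transfer proteins (2 of 67, 0.0412) held more fallen genes than the 0.178% of all genes. These rest on few genes, of which limma did not call AT1G06830 and AZI1 (adjusted p = 0.0944 and 0.242) and lost GRXS13 without the PA library of higher or of lower size factor (0.107 and 0.286). LAC5 and LAC12, laccases that can polymerize lignin units, rose by 2.62 and 3.16 with PA and by 4.22 and 4.01 with ABA in the authors' deposited table.

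Reads assigned to no gene made 48.2% to 48.5% of the normalized total, and 2 explanations were tested, the strand test chosen after the value was seen and the genomic DNA test written before. If a kit that does not mark strand was counted with a strand setting, genes lying inside exons of a gene on the other strand should carry reads in proportion to that gene: over 216 such genes observed and expected log2 reads had r = 0.574, against at most 0.196 in 1000 shuffles and 0.380 for the nearest gene without overlap. A first form of this test, the median of observed over expected (-0.16), was not decisive, since random genes gave up to 0.23. If genomic DNA made up the unassigned reads, few genes would lie far below its density, but 31.6% of 26712 coding genes lay more than 10-fold under it. The prediction also held that genes inside exons on the same strand carry almost no reads. Of 20 such genes 14 had 0 reads, against 7 of the 216 on the other strand. Ambiguous reads made 0.539% of gene and ambiguous reads in mock, where opposite-strand overlaps would hold 3.67% by read density. These values go with counting by strand but do not show whether the kit marked strand. The r of 0.574 goes with the strand setting, which remains a hypothesis. AT3G20380 goes the other way: its partner on the other strand would give 173 normalized counts, above its own mean of 74.9. It lay at -4.80 with ABA while the partner lay at -0.06. If the hypothesis holds, the values of genes overlapping on opposite strands may mix both genes.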
